A study of Homo sapiens with 2 samples.

How the data were processed

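Open chromatin was mapped by DNase-seq in primary human tracheal epithelial cells, in which DNase I cuts accessible DNA and the cut ends are sequenced. The 2 samples are labelled as biological replicates of untreated adult cells and form 1 group, so the design holds no contrast between conditions. The processed data are 1 deposited peak list for the whole series, with no column for either sample. Agreement between the replicates therefore could not be measured, and no value below carries a replicate error. The read depth of each sample is unknown from this list.

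The submitters' processing notes name BWA and the genome build hg19 (GRCh37). The peak caller, its smoothing, its filters and whether the replicates were pooled before or after calling are not given in the sources used here. The deposited list has the narrowPeak layout. It gives for each peak a start, an end, a summit, a signal, a −log10 p and a display score. The deposited signal is taken here as a peak height. The scaling of the signal is not stated by the authors, so it is used only to rank peaks and to compare medians within this list. The deposited −log10 p of the authors ran from 1.3, a p of 0.050, to a ceiling of 16, which was shared by 1672 peaks (1.13%). It followed the signal in rank across peaks (Spearman rho 1.000) and was not used further. The deposited score of the authors ran from 512 to 1000, with 16496 peaks (11.2%) at the ceiling, and was not used to rank peaks for that reason. The track title inside the deposited file names sites selective for tracheal cells without NHEK, which are epidermal keratinocytes. The peaks of each chromosome are numbered consecutively from 1. Neither fact decides whether the list is the complete peak set or a selected part of it, and all shares below are shares of the list as deposited.

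All values were computed on the 22 autosomes. Sex chromosomes were left out because the cells come from people. Coordinates are hg19 and are printed 1-based. The gene table at hand was built on a later assembly, and coordinates were not converted, so no peak was assigned to a gene, promoter or sequence. For this reason the planned tests of peak location, of open promoters, of 17 gene lists, of 33 sequence motifs, of base composition and of density against gene density were not analysed here, and the parts of the naming rule that choose genes could not be applied. The rest of that rule, fixed before the data were examined, names the 10 autosomal peaks of highest signal and the 5 runs with the most peaks. The 10 densest windows and the long peak-free stretches were listed after the data had been examined.

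Density was the number of peaks per Mb between the first and the last peak of an autosome, with a 95% interval from 1000 bootstrap draws of 5 Mb blocks. Clustering was the share of peaks with a neighbour less than 3 kb away, edge to edge. It was compared with 100 random placements of the same peak widths, without overlap, between the first and last peak of each autosome. The test was a one-sided permutation test whose smallest p is 0.0099. Peaks joined by successive gaps under 3 kb form a run. Peaks in runs of 3 or more were compared with isolated peaks by the difference of median signal, with a two-sided permutation test of 100000 resamples across peaks and a 95% interval from 200 draws of 5 Mb blocks. Peaks are not replicates, and these p-values describe this list only. Further quantities were added after the data had been examined. One is the ratio of peak density in the terminal 5 Mb of chromosomes to that in the remainder. It was averaged geometrically over autosomes, with an interval from 1000 draws of autosomes and a two-sided sign-flip permutation test of 100000 resamples over autosomes. Stretches of 1 Mb or more without a peak were left out of the lengths, and the start of an autosome counted as an end only where the first peak lay within 1 Mb of base 1, which gave 39 ends. The other is the rank correlation of the signals of neighbouring peaks, against 100 shuffles of the signals within each autosome. Benjamini-Hochberg adjustment was made over the 5 tests.

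The code was checked on simulated data. For random placement of 147828 peaks the clustering share was 30.6%, against 30.7% over its own placements, and the density ratio at chromosome ends was 1.00. All 200 planted runs of 25 weak peaks were found among 152828 simulated peaks, which their gaps under 3 kb made certain. The random data came from the same placement procedure as the comparison. These checks therefore concern the code and not how the procedures behave on real peaks. Alternatives covered the signal threshold, the neighbour distance, the merging of close peaks, the placement region and the length of the chromosome ends. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.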

Results

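DNase-seq was used to map open chromatin in cultured human tracheal epithelial cells, with the aim of locating candidate regulatory elements for genes of the airway lining. The 2 samples were biological replicates of 1 untreated group, and 1 peak list was deposited for both. The list held 147828 peaks on the 22 autosomes, which covered 65.6 Mb, or 2.35% of the 2789 Mb between the first and last peak of each autosome. Read depth was unknown, and values of single peaks had no replicate error. Whether the list is the complete peak set or a selected part is also unknown, so open sites below are listed peaks only. Spreads are given over autosomes.

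Most listed peaks were narrow and of low signal, and peaks of higher signal were wider. The median peak was 307 bp wide (SD of the medians of autosomes 16.8, n = 22), with a lower quartile of 184 bp and an upper quartile of 508 bp. The median signal was 0.0610 (SD 0.00178, n = 22) on the authors' scale. It stood close to the lowest listed value of 0.0374 and far below the highest, 1.83. Peaks in the strongest 25% by signal held 52.3% of the covered length. Their median width was 695 bp (SD 51.3, n = 22), against 125 bp (SD 4.23, n = 22) for the weakest 25%. Across peaks, signal and width rose together (Spearman rho 0.907, SD 0.00861 over 22 autosomes). How the unknown caller set the peak edges may contribute to this, which was not tested. Peaks of 2000 bp or more numbered 2642, or 1.79% of the list. They made up 11.4% of the covered length, and their median signal was 0.349, against 0.0601 for narrower peaks.

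**Figure D1:**
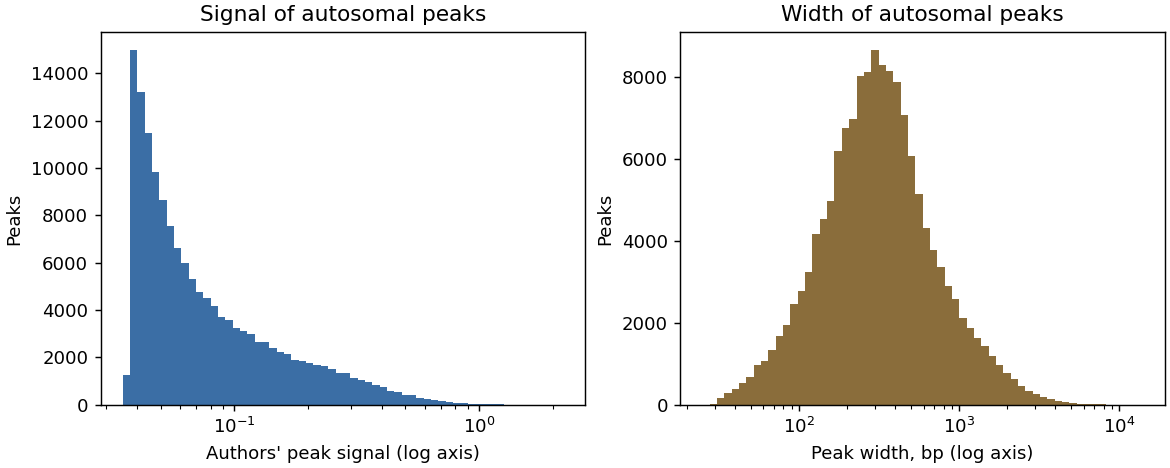
Number of autosomal peaks by the authors' peak signal (left) and by peak width in bp (right), both on log axes. Signals pile up just above the lowest listed value of 0.0374, while widths form 1 hump around the median of 307 bp.

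The 10 strongest autosomal sites had signals from 1.22 to 1.83, against a median of 0.0610. The strongest lay on chromosome 17 from 31149222 to 31150130. It was 909 bp wide, had a signal of 1.83 and had no neighbour within 3 kb. The next was a 2707 bp site on chromosome 9 from 140093446 to 140096152, with a signal of 1.64. A site of nearly equal signal, 1.63, lay on chromosome 2 from 127821382 to 127823130, inside a run of 15 peaks. Chromosome 19 held a site from 6278034 to 6280580 with a signal of 1.46 and a site from 3625947 to 3627690 with a signal of 1.22. Chromosome 1 also held a pair. The site from 156186035 to 156186836 had a signal of 1.45 and was only 802 bp wide, the narrowest of the 10. The site from 17274583 to 17276180 had a signal of 1.39. The remaining sites lay on chromosome 11 from 66055305 to 66057702 (signal 1.32), on chromosome 22 from 38053593 to 38055913 (1.29) and on chromosome 20 from 61887066 to 61888235 (1.26). Apart from the site on chromosome 17, all of them belonged to runs of 3 to 15 peaks.

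Open sites were spread unevenly over the chromosomes. The mean over autosomes was 60.9 peaks per Mb (SD 30.5, n = 22). Chromosome 22 had the highest density, with 149 peaks per Mb (95% block bootstrap interval 113 to 186). Chromosome 19, the most gene-dense human chromosome, followed with 131 peaks per Mb (86.3 to 179), and chromosome 17 with 106 (78.2 to 137). The order of these chromosomes was not tested, and the interval of chromosome 22 overlaps those of chromosomes 19 and 17. The lowest densities were on chromosome 4, with 31.7 peaks per Mb (21.999 to 46.0), and on chromosome 13, with 32.2 (22.4 to 45.0). Both are known as gene-poor chromosomes. The density of chromosome 22 was 4.69 times that of chromosome 4 (95% interval 3.01 to 7.18). With peak-free stretches of 1 Mb or more left out of the lengths it was 4.23 times. When each run of peaks was counted once, the fold between densest and sparsest autosome was 2.89, below that interval. Of the strongest 50% of peaks, chromosome 22 had 69.5 per Mb and chromosome 19 had 67.5. Of the strongest 25%, chromosome 19 had 40.7 per Mb and chromosome 22 had 39.2, a difference that was not tested. Of the weakest 25%, chromosome 22 had 43.4 per Mb and chromosome 19 had 33.2. Peaks covered 7.16% of chromosome 19 and 7.10% of chromosome 22, against 1.28% of chromosome 13.

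**Figure D2:**
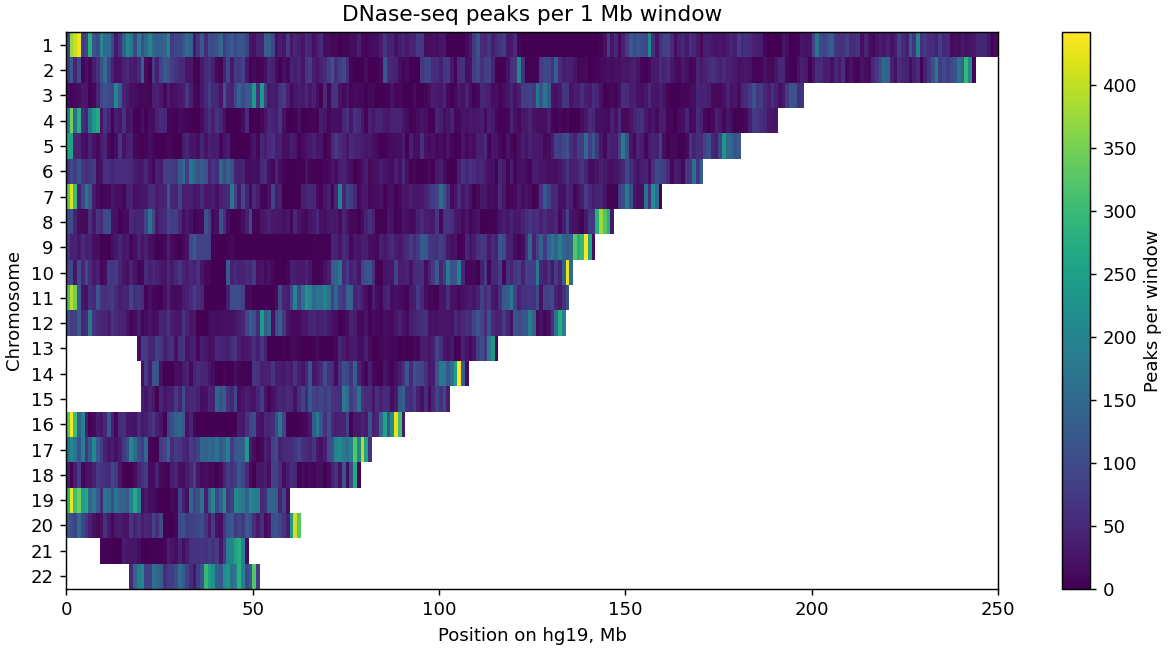
Peaks per 1 Mb window along the 22 autosomes on hg19, from 0 to 442 peaks (colour); white marks positions outside the first and last peak. The brightest windows lie at the ends of chromosomes such as 1, 7, 9, 10, 14, 16, 19 and 20, and dark stretches without peaks cross the middle of chromosomes 1, 9 and 16.

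At the scale of 1 Mb, the median window held 35 peaks (lower quartile 15, upper quartile 67), and 122 of 2807 windows held none. Windows ran from the first to the last peak of each autosome. The variance over windows was 67.4 times the mean. The densest 140 windows, 4.99% of all, contained 23.2% of all peaks. Of these, 67 windows (47.9%) lay within 5 Mb of a chromosome end, as did 211 of all windows (7.52%). The densest window, on chromosome 14 from 105000001 to 106000000, held 442 peaks, of which 86 were among the strongest 25%. Windows on chromosome 9 from 139000001 (439 peaks), chromosome 16 from 1000001 (438) and chromosome 1 from 3000001 (433) came next. The remainder of the 10 densest windows held 407 to 429 peaks and lay on chromosomes 1, 7, 10, 16, 19 and 20. All 10 were within 2.29 Mb of the outermost peak of their chromosome.

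Chromosome ends carried more open sites than the rest of the same chromosome. The terminal 5 Mb of 39 ends held 30033 peaks, 20.3% of the list, on 7.59% of the length. Averaged over autosomes, their density was 2.80 times that of the remainder (95% interval 2.31 to 3.33, n = 22; sign-flip permutation p = 2e-05, Benjamini-Hochberg adjusted p = 3.3e-05). The ratio was above 1 on 22 of 22 autosomes. With each run of peaks counted once it was 1.59 (1.43 to 1.79), below that interval, and with peaks within 500 bp merged it was 2.38 (2.02 to 2.78). Without merging, it was largest on chromosome 21, at 5.41, and smallest on chromosome 15, at 1.15, and chromosome 3, at 1.19. Sites of every strength were denser at the ends, but the weakest 25% more so than the strongest 25%. The ratio was 3.68 (2.92 to 4.49) for the weakest 25% of peaks and 2.32 (1.94 to 2.76) for the strongest 25%. The weak ratio exceeded the strong ratio by 1.59 times (1.43 to 1.76) and on 21 of 22 autosomes (permutation p = 2e-05, adjusted p = 3.3e-05). The median signal was 0.0537 at the ends (SD 0.00461 over autosomes) and 0.0633 elsewhere (SD 0.00159). This comparison was chosen after the densities had been seen.

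**Figure D3:**
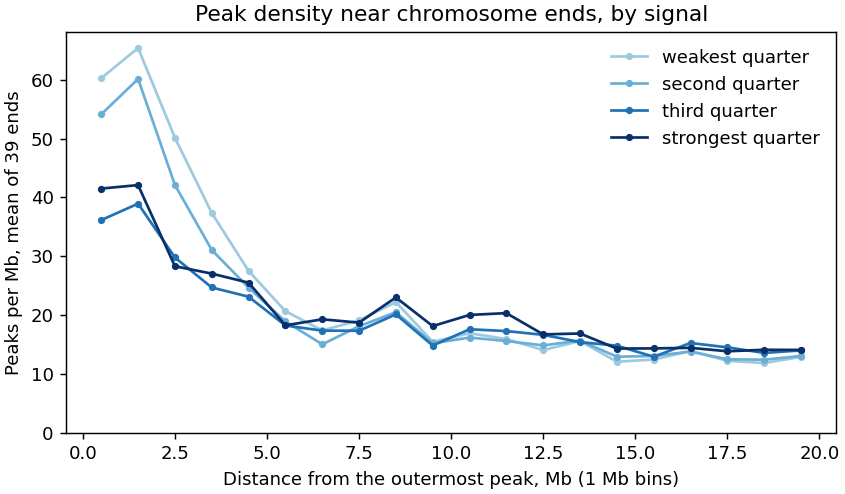
Mean number of peaks per Mb over 39 chromosome ends, in 1 Mb bins from the outermost peak inwards, for 4 equal classes of signal (lines). The weakest class holds 60.3 per Mb in the outermost bin, 65.4 in the next and 12.9 in the bin that starts 19 Mb inwards. The strongest class holds 41.5, 42.1 and 14.1 in the same bins.

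Listed peaks occurred in groups. Of all peaks, 62.2% had a neighbour within 3 kb (SD over autosomes 8.57, n = 22), against a mean of 30.7% in 100 random placements of the same peaks (range 30.4 to 31.1). The observed share was 2.03 times the random one (one-sided permutation p = 0.0099, the smallest these placements can give, adjusted p = 0.0099). It ranged from 49.5% on chromosome 13 to 78.9% on chromosome 19 and 79.1% on chromosome 22. Part of this share goes with the uneven density along chromosomes. With each peak placed at random within its own 1 Mb window the share was 46.0%, and the observed value remained 1.35 times as high (p = 0.0099, permutation).

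**Figure D4:**
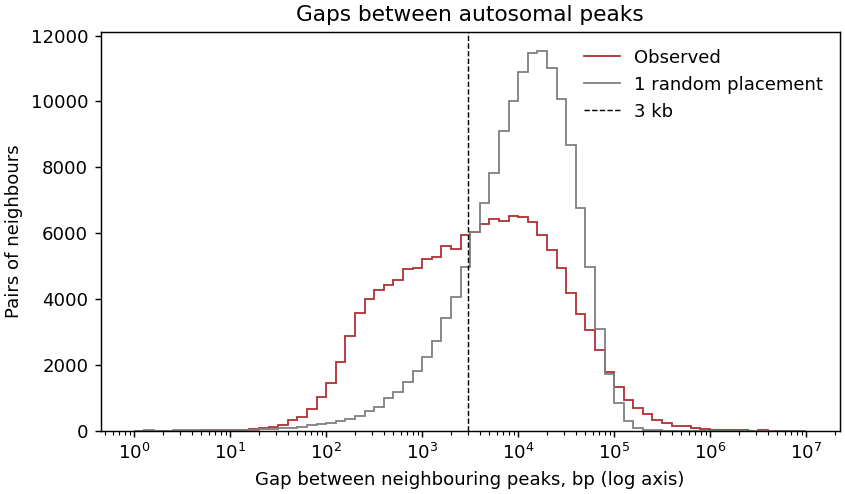
Number of pairs of neighbouring autosomal peaks by the gap between them in bp (log axis), observed (red) and in 1 random placement of the same peaks (grey), with 3 kb marked. The observed pairs outnumber the random ones over most gaps below 3 kb but not at the shortest gaps, and the median observed gap is 4033 bp.

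Runs of 3 or more peaks numbered 11706 and contained 63881 peaks, 43.2% of the list (SD 10.3 over autosomes). Isolated peaks numbered 55857, or 37.8% (SD 8.57). The 237 runs of 20 or more peaks were concentrated at chromosome ends, with 163 of them in the terminal 5 Mb. The largest run had 97 peaks over 135 kb of chromosome 16, from 88442855 to 88578097. Peaks covered 39.2% of it, and 13 of them were among the strongest 25%, with a highest signal of 0.953. A run on chromosome 20 from 62047045 to 62122640 held 65 peaks with a highest signal of 0.414. A run on chromosome 19 from 1221470 to 1319070 held 64 peaks, which covered 54.7% of 97.6 kb and included 18 of the strongest 25%. Runs of 63 peaks lay on chromosome 14 from 105609833 to 105693071 and on chromosome 17 from 79353272 to 79439448, with highest signals of 0.647 and 0.550.

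Runs of 20 or more peaks together held a smaller share of strong peaks and a larger share of weak ones than isolated peaks did. Single runs varied. Among the 5 largest, the peaks in the strongest 25% ranged from 7 of 65 on chromosome 20 to 18 of 64 on chromosome 19. Peaks in runs of 3 or more had a median signal of 0.0564, against 0.0642 for isolated peaks. The difference was -0.0078 (95% block bootstrap interval -0.0086 to -0.0067; permutation p = 1e-05, the smallest these resamples can give, adjusted p = 3.3e-05) and had the same sign on 22 of 22 autosomes. With runs joined over gaps of up to 10 kb the difference was -0.0027 (-0.0040 to -0.0017), with the same sign on 19 autosomes. Peaks in runs were wider, with medians of 327 bp and 287 bp. Among peaks of the middle widths, between the quartiles, the difference in median signal was -0.0138 (-0.0147 to -0.0132). The share among the strongest 25% was 24.1% in runs and 24.5% for isolated peaks. Its direction turned with gaps of up to 10 kb (25.6% and 22.1%), with peaks within 500 bp merged (29.1% and 27.5%) and without the terminal 5 Mb (26.4% and 24.4%). Among peaks of the middle widths the direction stayed, at 9.19% and 16.3%. In runs of 20 or more, 15.2% of peaks were among the strongest 25% of the list and 32.3% among the weakest 25%, against 24.5% and 22.3% of isolated peaks. Runs of 3 to 4 peaks differed from this, with 28.9% among the strongest and 24.97% among the weakest. The highest peak of a run of 20 or more had a median signal of 0.476. With signals shuffled among all peaks this median was 0.402 on average (range 0.368 to 0.427 over 100 shuffles), so the highest peaks of these largest runs were stronger than their number alone gives. The observed median was also above the shuffled range for isolated peaks, at 0.0642 (0.0604 to 0.0614), and for runs of 2, 3 to 4 and 5 to 9 peaks. For runs of 10 to 19 peaks the observed 0.313 lay within the range of 0.285 to 0.319. Among the strongest 50% of peaks, with runs formed anew, the difference was 0.0068 in the other direction. This setting changes both the peaks compared and the membership of runs, and selects on the signal itself.

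**Figure D5:**
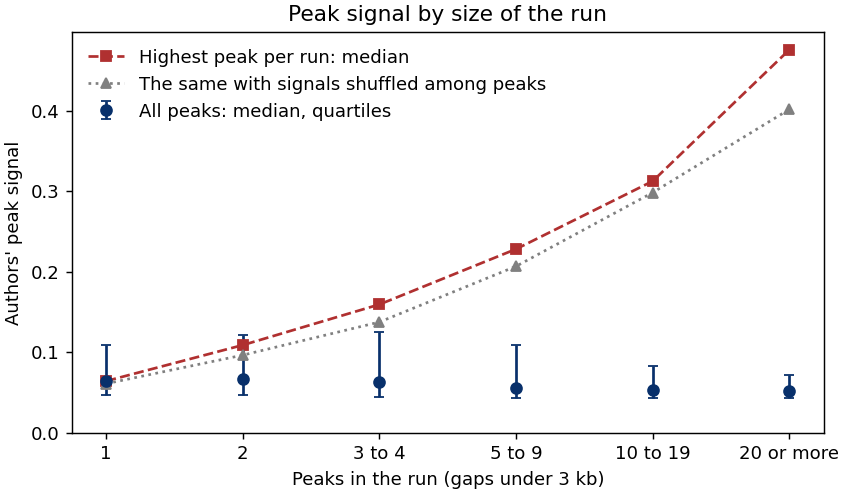
Authors' peak signal by the number of peaks in a run, as median and quartiles of all peaks (blue), median of the highest peak per run (red) and the same median with signals shuffled among peaks (grey). The median of all peaks is 0.0642 for isolated peaks, 0.0664 in runs of 2, 0.0630 in runs of 3 to 4 and 0.0516 in runs of 20 or more, while the median of the highest peak reaches 0.476.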

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

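Of 26 alternatives, 23 kept their result: where it had a test, its direction and its side of 0.05, for the fold in density, its 95% interval, and for the number of peaks, a change under 1.5 times. For results with a test this rule does not judge size. A density ratio at chromosome ends of 1.59 counted as kept, although it lay below the 95% interval of 2.31 to 3.33. Those at chromosome ends and for neighbouring signals, and some of those for runs, clustering and density, were chosen after seeing the data. Keeping the strongest 50% of peaks left 73914 peaks by construction. With runs formed anew among them, the difference in median signal between runs and isolated peaks turned from -0.0078 to 0.0068, and the cause was not tested. The difference was -0.0027 with gaps of up to 10 kb and -0.0138 among peaks of the middle widths, between the quartiles. Counting each run once lowered the fold between the densest and sparsest autosome from 4.69 to 2.89. Runs form more readily where peaks are dense, so this drop is partly built in, and whether anything else contributes was not tested. Among the strongest 25% of peaks the fold was 6.15, with chromosome 19 the densest. The clustering ratio ranged from 1.22 (neighbours within 10 kb) to 2.64 (a random 50% of peaks left out). The density ratio at chromosome ends ranged from 1.59 (runs counted once) to 3.68 (weakest 25%), and from 2.71 to 2.92 without 1 autosome. In the terminal 2 Mb the ratio of chromosome 3 was 0.967, and in the terminal 10 Mb that of chromosome 15 was 0.980. Replicates could not be left out, because the list holds no values per sample. Every alternative planned for peak location, promoters, gene lists and motifs, that of gap-free chromosome length, and those of promoter against distal signal were not run for lack of an hg19 annotation or sequence. Depth and the peak caller's settings are unknown, and the list may be a selected part of the peak set. Sites absent from it, weak or strong, therefore cannot be called closed.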

Other observations

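The tests of chromosome ends and of neighbouring signals were chosen after the peak list had been examined; the 5 tests of explanations were set down after the patterns had been seen and before their own values were, and the settings they use were added after the data had been examined. Long stretches without a listed peak marked the other extreme of the map; some span unsequenced parts of the assembly, so they are not shown to be closed. Between neighbouring peaks there were 93 peak-free stretches of 1 Mb or more, 220 Mb in all. Stretches before the first or after the last peak of an autosome were not counted. The longest of those counted between peaks spanned 22.3 Mb of chromosome 1 from 121315883 to 143647329. Next came 19.6 Mb of chromosome 9 from 46862212 to 66458311 and 12.2 Mb of chromosome 16 from 34432866 to 46588392. These stretches include the centromeres and large heterochromatic blocks of their chromosomes. Chromosome 4 had 10 such stretches between peaks, the most of any autosome, and chromosomes 15 and 22 had 0. These counts leave out chromosome starts. On chromosomes 13, 14, 15, 21 and 22 the first peak lay 1 Mb or more from base 1. On chromosome 13 the longest between peaks, 3.38 Mb, ran from 62455243 to 65838327. Stretches of 2.69 Mb from 54603633 to 57295128 and of 2.05 Mb from 58206193 to 60252458 lay on the same arm. On chromosome 21, no peak was listed from 19297611 to 21791930, a stretch of 2.49 Mb.

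Neighbouring sites were only slightly alike in strength. The rank correlation of the signals of adjacent peaks was 0.0567 across 147806 pairs (SD 0.020 over 22 autosomes), outside the range of 100 shuffles within autosomes, -0.00580 to 0.00693 (permutation p = 0.0099, adjusted p = 0.0099). Among adjacent peaks more than 3 kb apart it was 0.0589. Peaks are not independent replicates.

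The excess of open sites at chromosome ends (density ratio 2.80) was weighed against technical explanations; the design holds 1 group, so no biological explanation was tested for this pattern or the next. If it came only from weak peaks near the calling threshold, the strongest 25% of peaks would show a ratio of 1.5 or lower; their ratio was 2.32 (95% interval 1.94 to 2.76), which argues against this as the whole cause, although the weak peaks had the larger excess. If it came from wide sites called as several peaks within 500 bp, merging these would bring the ratio to 1.5 or lower; it was 2.38 (2.02 to 2.78), which argues against this as the whole cause. Counting each run once gave 1.59 (1.43 to 1.79), whose interval includes the 1.5 set for that test. Runs form more readily wherever peaks are dense, so this drop is partly built in and does not decide whether sites split over longer gaps contribute. Higher gene density and higher GC content near chromosome ends are candidate explanations too, biological and technical, and neither was tested without an annotation or sequence of hg19.

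The lower median signal of peaks in runs (difference -0.0078) was weighed in the same way. If wide sites called as several peaks were the cause, merging peaks within 500 bp and keeping the highest signal would bring the difference to 0 or above; it was -0.0059 (95% interval -0.0071 to -0.0048; permutation p = 1e-05). If the dense chromosome ends were the cause, the difference would end without the terminal 5 Mb; it was -0.0051 (-0.0061 to -0.0041; permutation p = 1e-05) and had the same sign on 19 of 22 autosomes. The value without the ends argues against the ends as the whole cause. The merged value does not decide on split sites. Merging reached only gaps of up to 500 bp, while runs join gaps under 3 kb. Sites that it joins can also become isolated peaks with their highest signal, and the isolated median was 0.0673 after merging and 0.0642 before. The turn to 0.0068 among the strongest 50% of peaks, a setting that also forms the runs anew, leaves open that weak peaks are listed more readily near other open sites, a hypothesis that may concern the caller or the chromatin and was not tested further.

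The listed summit lay slightly to the left of the centre of the peak. The median offset was -4.5 bp (SD 0.284 over 22 autosomes), and 68.3% of all summits lay left of centre. In the narrowest 10% of peaks this share was 96.8%, with a median offset of -5.5 bp. In the widest 10% it was 50.8%, with a median offset of -9.5 bp (SD 21.8). Summits of neighbouring peaks were never closer than 159 bp, and only 4 pairs were closer than 200 bp. In classes of equal width, the most frequent gap between neighbouring peaks was 200 to 250 bp, with 3450 pairs, against 1205 pairs with a gap of 900 to 950 bp.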
